A study of Mus musculus with 9 samples.

How the data were processed

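RNA was measured in 9 samples of GFP-labelled 3LL cells, the murine Lewis lung carcinoma (LLC) line, in 3 groups of 3. The cells of 1 group were grown as a monolayer in culture dishes for 7 days. Those of the other groups were transplanted under the skin or into the lung, and GFP-positive cells were isolated 7 days after transplantation, per the labels. The series text gives the lung model a further short abbreviation that it does not spell out, and it was left as it stands. Per the labels' protocols, total RNA was purified on spin columns, its integrity was read on a Bioanalyzer (RNA integrity number, RIN, 7.5 to 8.6), and fragmented sense-strand cDNA was labelled with biotin for a 1-colour whole-transcript array. The strain given is C57BL/6. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the 3 samples of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

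The authors deposited 1 table of log2 signals, with 28846 rows and 1 column per array. Normalization method, software and genome build are not given in the sources used here, so no coordinates are printed. The values were already on a log2 scale (1.56 to 19.7) and were used as deposited. The array medians over all rows lay between 5.26 and 5.43, close to the medians of the negative controls (4.77 to 5.02), so they do not show how expressed genes were scaled. The upper quartile over genes ran from 8.20 to 8.68 and was highest on the lung arrays (8.55 to 8.68). A change common to most transcripts therefore could not be told from a difference in scaling, and such a difference may enter the calls. Of the rows, 22206 were gene features, 5222 negative controls, 1324 positive controls and 94 other controls. A platform annotation table gave 19572 features 1 gene symbol and 0 features several, while 2634 gene features had no symbol here. All 19572 symbols were looked up through their gene numbers in a RefSeq gene table of mouse assembly GRCm38.p6, and 0 changed. For the 55 genes with several features, the feature with the highest mean over the 9 arrays was used, which left 19505 genes. There was no filter on level. The deposited table holds no detection call. As a guide to background, the 90th percentile of the negative controls was taken on each array (7.20 to 7.73 on the log2 scale). A gene under it on all 3 arrays of a group was read as not well above background, and its fold change then rests on background on that side. The bound given as "at least" for such a gene is the mean of the brighter group minus the mean of that percentile on the arrays of the dimmer group.

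Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust fitting) on all 9 arrays in 1 fit with 3 group means, with 6 residual and 7.08 prior degrees of freedom. The contrasts were lung against subcutaneous, lung against dish and subcutaneous against dish. Tests were two-sided, with Benjamini-Hochberg adjustment over the 19505 genes, and a gene was called at an adjusted p under 0.05. "Rose" and "fell" are used only of called genes and lists. Values are log2 signals as mean ± SD with n = 3 unless stated otherwise, and differences are log2 fold changes.

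Before the data were examined, 40 gene lists were written with 478 genes, of which 442 were measured and 0 stood in more than 1 list. The other members were not analysed here. Of the lists, 18 hold markers of other cell types that a tumour sample could carry: alveolar type II, alveolar type I, airway secretory, ciliated, endothelium, alveolar macrophage, monocyte and macrophage, neutrophil, T and NK cell, B and plasma cell, dendritic cell, fibroblast, smooth muscle and pericyte, mesothelium, keratinocyte, adipocyte, skeletal muscle, and erythroid and platelet. The other 22 hold cell programs: lung lineage transcription factor, epithelial identity, mesenchymal identity, collagen and extracellular matrix, matrix protease, TGF-beta target, DNA replication, mitosis, hypoxia, glycolysis, oxidative phosphorylation, cholesterol biosynthesis, type I interferon response, interferon-gamma response, MHC class I, MHC class II, inflammatory cytokine and NF-kB, complement, immediate early, unfolded protein response, amino acid stress (ATF4) and p53 target. Lists were tested with limma's camera, which asks whether a list moved relative to the other genes, with its preset correlation between genes of 0.01 and adjustment over the 40 lists. The same test was repeated with the correlation estimated for each list. limma's fry was run as well. Its directional p asks whether the members moved on balance one way, its mixed p whether they changed in either direction, and neither sets a list against other genes.

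The rule for the genes named was fixed before the data were examined. For each comparison it takes, among called genes whose 3 values in 1 group all lay above the 3 of the other, the 10 with the highest and the 10 with the lowest log2 fold change, without unnamed gene models. From each list described it takes up to 4 called members with the largest changes, or the 2 with the largest changes where 0 were called. For the overlap of the 2 transplanted groups it takes 5 genes per shared direction and up to 5 with opposite changes. A gene outside the rule is said to be so where it appears.

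Alternatives set before the data were examined were quantile normalization of the log2 values, a filter at the 25th percentile of mean signal, the mean of a gene's features, an intensity trend, array weights, RIN as a covariate, the replicate number as a block, a fit of only the 6 arrays compared, a 2-fold threshold, fry, the estimated correlation, and leaving out each array in turn. A covariate for the level of very long mRNAs was added after seeing the data. It was computed from the same log2 signals, as the median deviation of those genes on each array. Its mean was -0.42 in dish, -0.19 in subcutaneous and 0.52 in lung samples. RIN differed between the groups as well, so either covariate can also take away part of a group difference. The gene and list tests were tested on simulated data: arrays with the spread of the real ones and 200 changed genes were made for each comparison. Of changed genes with a log2 fold change of 1, 31.3% were called in lung against subcutaneous, 29.9% in lung against dish and 28.4% in subcutaneous against dish. At a log2 fold change of 2 the shares were 100%, 97.0% and 97.0%, and at 3 they were 100% in all 3 comparisons. The false calls made up 2.52%, 5.63% and 5.49% of the calls. The real comparisons called 1322 to 2927 genes, which loosens the adjusted threshold, so the shares above do not carry over to the real fits. Simulated genes were drawn independently, so the preset correlation of the list test was not checked. For arrays, the number of samples limits the precision.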

Results

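Array profiles of 19505 genes were compared between 3 dish cultures of Lewis lung carcinoma cells, a transplantable mouse lung tumour line, 3 samples of GFP-positive cells isolated from subcutaneous tumours and 3 isolated from the lung. Arrays of 1 group resembled each other more than those of other groups. Pearson's r across genes, which are not independent replicates, was 0.985 to 0.987 among the dish arrays, 0.980 to 0.983 among the subcutaneous arrays, 0.980 to 0.991 among the lung arrays, and 0.958 to 0.977 between groups. No pair of arrays was identical: the smallest of the largest differences between 2 arrays was 2.38 on the log2 scale. The first principal component (36.1% of the variance) set the subcutaneous arrays apart from the others, the second (24.8%) parted dish from lung, and the third (9.18%) parted lung replicate 3 from lung replicates 1 and 2. On each array, 28.0% to 34.4% of the genes lay above the 90th percentile of the negative controls. Technical measures differed between the groups as well. The mean of the bacterial hybridization controls was 12.01 ± 0.15 (SD, n = 3) on the dish arrays, 12.83 ± 0.11 on the subcutaneous arrays and 11.35 ± 0.35 on the lung arrays, and the mean RIN was 8.50 ± 0.10, 7.97 ± 0.57 and 8.17 ± 0.23. In a list of 75 genes with very long mRNAs, chosen after the data had been seen, 24 genes were higher in lung than in subcutaneous samples, 24 higher in lung than in dish samples and 14 higher in subcutaneous than in dish samples (medians 0.70, 1.12 and 0.23). On lung replicates 1 and 2 this list stood 0.97 (median, log2) above lung replicate 3.

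The first comparison asked how tumour cells in the lung differed from those under the skin, and whether genes typical of the lung were among those that were higher, which is the topic the series names. The largest rise was that of Sftpc, the surfactant protein made by alveolar type II cells, at 15.14 ± 1.51 (SD, n = 3) in lung samples against 5.38 ± 0.37 in subcutaneous ones, a log2 difference of 9.76 with a standard error of 0.55 (adjusted p = 3.31e-06). Other large rises were those of another surfactant gene, Sftpa1 (6.01), the club cell secretory gene Scgb1a1 (5.08), the cytokine Il24 (4.18) and the carbonyl reductase Cbr2 (3.64). These genes were not well above background in the subcutaneous samples, so the differences are at least 7.63 for Sftpc, 2.48 for Sftpa1, 2.43 for Scgb1a1, 3.57 for Il24 and 1.82 for Cbr2. Without lung replicate 3 the bounds are 1.53 for Sftpa1, 0.56 for Scgb1a1 and 0.12 for Cbr2. Scgb1a1 was under background on lung replicate 1, without which its bound is 4.25. In the alveolar type II list, 6 of 11 measured genes rose and 0 fell, with 6 adjusted over the list alone. The median log2 fold change of its members was 1.30 (camera adjusted p = 0.000349, adjusted p = 0.471 with an estimated correlation). Among them, Sftpb rose by 2.79 and the lung chemokine Cxcl15 by 3.45, both above background on lung replicate 3 and not on lung replicates 1 and 2. Of 7 alveolar type I genes, the tight junction gene Cldn18 (3.24, at least 1.31) and Ager (1.39) rose and the membrane protein gene Emp2 fell (-1.80), and the list did not pass (adjusted p = 0.938). Scgb1a1 was the 1 of 10 airway secretory genes that rose, and that list did not pass with all arrays (adjusted p = 0.162) but passed without lung replicate 1 (adjusted p = 0.00245) or lung replicate 2 (adjusted p = 0.041), or with the level of very long mRNAs as a covariate (adjusted p = 4.30e-09). The list mean was 4.42, 5.15 and 8.17 on lung replicates 1, 2 and 3, and 4.44 to 4.67 on the subcutaneous arrays. The covariate likewise parts lung replicate 3 (-0.17) from lung replicates 1 and 2 (0.85 and 0.88). These passes therefore rest mostly on lung replicate 3. Ager was above background on lung replicate 2 alone and lost its call without it (adjusted p = 0.0535), and Scgb1a1 lost its call without subcutaneous replicate 2 (adjusted p = 0.0535). Without lung replicate 3 the difference was 3.21 for Scgb1a1 and 1.94 for Cbr2, and Cbr2 lost its call without subcutaneous replicate 1, 2 or 3 (adjusted p = 0.0521, 0.0571 and 0.0747). Of the 9 alveolar and airway genes that rose, 7 were highest on lung replicate 3. By limma, 0 of 10 lung lineage transcription factors rose and 0 fell, with 0 lower adjusted over the list alone and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.604). The largest differences among them were -0.95 for Sox9 (adjusted p = 0.156) and -0.77 for Foxp2 (adjusted p = 0.064, not well above background in either group). Foxp2 was called without subcutaneous replicate 2 (adjusted p = 0.0289), and Sox9, lung against subcutaneous, with the long-mRNA covariate (-2.06, adjusted p = 0.00955). Of the 10 factors only 1 was above background on the dish arrays, so the absence of calls says little about the others.

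**Figure D1:**
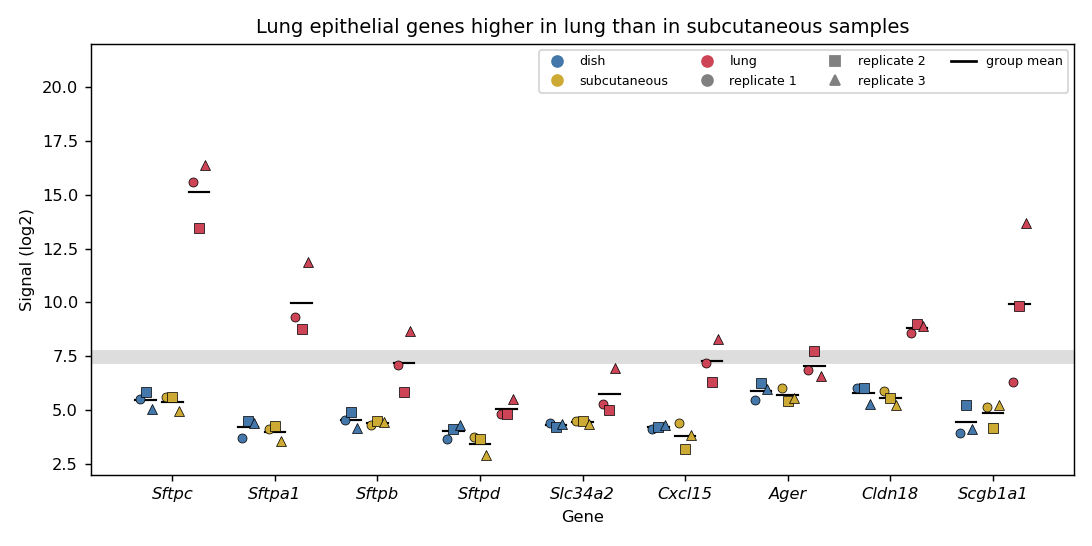
Log2 signal on each of the 9 arrays for the 9 alveolar and airway genes that were higher in lung than in subcutaneous samples (points, 1 per array with a symbol per replicate; black lines, group means). The grey band spans the 90th percentiles of the negative controls (7.20 to 7.73); Sftpc lies far above it on all 3 lung arrays and under it on the other 6, and Sftpd and Slc34a2, named after their values were seen, lie under it on all 9.

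Genes that answer to low oxygen were lower in the lung than under the skin. In the hypoxia list 9 of 13 genes fell and 0 rose, with 12 adjusted over the list alone. The median was -1.42 (camera adjusted p = 3.40e-08, adjusted p = 0.471 with an estimated correlation). The stress gene Ndrg1 fell by 4.18, the peptide hormone Adm by 3.34, the mitophagy gene Bnip3 by 3.09 and the oxygen sensor Egln3 by 2.87. Sterol synthesis genes were lower too: 8 of 13 fell and 0 rose (8 adjusted over the list alone), among them the lanosterol demethylase Cyp51 (-3.03), Msmo1 (-2.70) and squalene synthase Fdft1 (-2.55). The median was -1.35 (camera adjusted p = 8.10e-07, adjusted p = 0.532 with an estimated correlation). Of the 11 MHC class I genes, 6 fell, among them the peptide transporter Tap1 (-1.79) and the light chain B2m (-1.54), and 1 rose, the other transporter subunit Tap2 (1.12, named after its values were seen), with 6 and 1 adjusted over the list alone. The median was -1.17 (camera adjusted p = 0.00443, adjusted p = 0.471 with an estimated correlation). Among 13 fibroblast markers 4 fell and 0 rose, with 5 adjusted over the list alone. The median was -0.47 (camera adjusted p = 0.0158, adjusted p = 0.471 with an estimated correlation). They include the matrix proteoglycans Lum, at 13.20 ± 0.72 in subcutaneous and 7.08 ± 0.61 in lung samples, and Dcn (-4.44), and Dpt (-2.31, at least 0.81). Mfap5, also among them, was not well above background in either group. Its call was lost without dish replicate 2, subcutaneous replicate 1 or 3, or any lung array (adjusted p = 0.0546 to 0.108). In the complement list 2 of 7 genes fell, C2 (-1.53) and C1s1 (-1.44), both not well above background in either group (2 adjusted over the list alone). The median was -0.41 (camera adjusted p = 0.0377, adjusted p = 0.471 with an estimated correlation). Ly6c1 (-5.52) and Ly6c2 (-4.52), near-identical copies whose separate values are uncertain, fell as well. Other large falls were those of the Wnt antagonist Dkk2 (-4.42), the matrix protein Thbs2 (-4.14), the angiogenic factor Pgf (-3.96), the claudin Cldn9 (-3.96) and the lipid phosphatase Lpin1 (-3.85); not well above background in lung samples, Thbs2 differed by at least 2.40, Cldn9 by at least 2.10 and Lpin1 by at least 1.62. Without subcutaneous replicate 3 the fibroblast and complement lists did not pass (adjusted p = 0.0523 for both), and the complement list also failed without subcutaneous replicate 1 (adjusted p = 0.0662) or lung replicate 3 (adjusted p = 0.0942), or with array weights (adjusted p = 0.062).

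Cell division genes were higher in the lung than under the skin. Of 14 mitosis genes 6 rose and 0 fell, with 10 adjusted over the list alone, among them the anaphase-promoting complex activator Cdc20 (2.83), the kinase Plk1 (1.53), the kinetochore motor Cenpe (4.67, at least 2.94) and the proliferation marker Mki67 (3.68). The median was 0.83 (camera adjusted p = 1.87e-05, adjusted p = 0.471 with an estimated correlation). In the DNA replication list 4 of 14 rose and 0 fell, with 6 adjusted over the list alone. The median was 0.64 (camera adjusted p = 0.00037, adjusted p = 0.617 with an estimated correlation). Examples are the origin licensing genes Cdc6 (1.99) and Mcm5 (1.45). The other called genes, Chaf1b and Mcm2, lost their calls without subcutaneous replicate 2 (adjusted p = 0.053 and 0.0794) or lung replicate 1 (0.0563 and 0.0872). Mcm2 also lost it without subcutaneous replicate 3 (0.0705) or lung replicate 2 (0.0952). Cenpe and Mki67 have very long mRNAs, as do the splicing factor Srrm2 (3.91) and the chromatin remodeller Bptf (3.67, at least 2.19, or 3.50 without lung replicate 3). On lung replicates 1 and 2 they stood above lung replicate 3, by 4.09 for Cenpe, 5.10 for Mki67, 2.85 for Srrm2 and 3.92 for Bptf. Mki67 lost its call without subcutaneous replicate 1, 2 or 3 (adjusted p = 0.0609, 0.0551 and 0.0561), lung replicate 1 (0.102) or lung replicate 2 (0.0914). Respiratory chain genes rose in part: 6 of 13 were higher and 0 lower (6 adjusted over the list alone), such as Sdha (1.73, at least 0.62) and Uqcrc1 (1.59). The median was 0.26 (camera adjusted p = 0.0377, adjusted p = 0.617 with an estimated correlation). Of the 13 amino acid stress genes 4 rose and 0 fell (4 adjusted over the list alone), such as the amino acid transporter Slc7a5 (1.53) and the folate enzyme Mthfd2 (1.52). The median was 0.39 (camera adjusted p = 0.0377, adjusted p = 0.617 with an estimated correlation). The respiratory list did not pass without subcutaneous replicate 1 (adjusted p = 0.0576), subcutaneous replicate 3 (0.0523) or lung replicate 3 (0.11), nor with the filter on dim genes (0.132) or array weights (0.0721). The amino acid stress list did not pass without subcutaneous replicate 2 (adjusted p = 0.121), subcutaneous replicate 3 (0.0529) or lung replicate 2 (0.0549), nor after quantile normalization (0.0664), with the filter on dim genes (0.132), with RIN as a covariate (0.0745) or with the long-mRNA covariate (0.115).

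Over all genes, 2927 of 19505 differed between lung and subcutaneous samples, 1797 higher in lung and 1130 lower. A difference of at least 2-fold was seen for 2247 of them. After quantile normalization 1405 were higher and 1248 lower, a more even split. The count was 1476 without lung replicate 1 and 1938 without lung replicate 2, and 1110 with the level of very long mRNAs as a covariate. Of the 40 lists 10 passed, 5 upward and 5 downward, 0 of the 40 with an estimated correlation (lowest adjusted p = 0.471 with an estimated correlation), where 2 had an unadjusted p under 0.05. By fry 12 lists moved on balance one way, the 10 among them. Without subcutaneous replicate 3, 6 lists passed.

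The remaining lists did not pass between lung and subcutaneous samples (adjusted p = 0.111 to 0.993), though single members did. Of the 15 epithelial identity genes, the keratin Krt18 fell (-2.98) and E-cadherin, Cdh1, rose (1.12; without subcutaneous replicate 1 or 3 or lung replicate 2, adjusted p = 0.0614, 0.052 and 0.0652). Among 9 mesenchymal identity genes 3 fell, such as S100a4 (-1.74) and vimentin, Vim (-1.53), and the transcription factor Twist2 rose (1.30, at least 0.70). The matrix protein Postn (-3.46, at least 0.76, or 0.35 without subcutaneous replicate 3) was 1 of 2 collagen and extracellular matrix genes of 15 that fell, while 1 rose. In the matrix protease list 4 of 12 rose, such as Adam8 (2.35, above background on lung replicate 3 alone) and the inhibitor Timp1 (1.62), and 2 fell, such as urokinase, Plau (-1.61); adjusted over the list alone the counts were 7 and 5. Cdh1 and Plau, like Gbp4 and Ciita, were not well above background in either group. Of 12 unfolded protein response genes 4 rose, such as Creld2 (2.38) and Sdf2l1 (1.34), and Dnajb9 fell (-1.28). In the p53 target list Phlda3 (3.44, at least 1.58) and the nuclease Aen (1.38, at least 0.54) rose and 1 of 11 fell. Glycolysis had 2 of 11 genes lower, among them Pgk1 (-1.31), and passed without lung replicate 1 (adjusted p = 0.0404), after quantile normalization (0.0364), with an intensity trend (0.0392) and with the long-mRNA covariate (0.0147). With that covariate the collagen (0.0147) and immediate early lists (0.0146) passed too. The type I interferon response list had 2 of 13 higher, Usp18 and Isg15, both not well above background in either group. Usp18 lost its call without subcutaneous replicate 2, lung replicate 1 or lung replicate 3 (adjusted p = 0.074, 0.0625 and 0.0593). Isg15 lost its call without dish replicate 1 (adjusted p = 0.0592), among other arrays. The interferon-gamma response list had 1 of 12 lower (Gbp4, -1.35), the MHC class II list 1 of 7 (its activator Ciita, -1.38) and the immediate early list 2 of 13 (Egr2 among them, -1.71, at least 1.09). By limma, 0 of 9 TGF-beta targets and 0 of 16 inflammatory cytokine and NF-kB genes were called, with 3 and 2 at an unadjusted p under 0.05. Calls appeared for Skil, lung against subcutaneous, without lung replicate 3 (1.01, adjusted p = 0.0357) or with array weights (0.0312). They also appeared for Cxcl2, lung against subcutaneous, without lung replicate 3 (2.30, adjusted p = 0.01) or with array weights (0.0454), and for Ccl2, lung against subcutaneous, after quantile normalization (-1.03, adjusted p = 0.04) or with array weights (0.0327).

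Among the markers of blood and stromal cell types few genes were called between lung and subcutaneous samples. In the alveolar macrophage list Plet1 fell (-1.92), 1 of 8. In the monocyte and macrophage list Lyz2, the lysozyme gene that alveolar type II cells also express, rose (2.33, at least 1.17, or 0.68, 2.35 and 0.49 without lung replicate 1, 2 and 3), and 2 of 14 fell, Ly6c2 and Cx3cr1 (-1.10, not well above background in either group; adjusted p = 0.0835 without lung replicate 1). Lyz2 was at 8.68 ± 2.05 on the lung arrays, and its call was lost when any of the 9 arrays but lung replicate 2 was left out (adjusted p = 0.061 to 0.178); without lung replicate 2 the difference was 3.51. Single genes also fell in the T and NK cell (1 of 13), dendritic cell (1 of 9, Ccr7, -1.52) and mesothelium lists (1 of 6), and 1 of 11 skeletal muscle genes rose. The T and NK cell gene Gzma was not well above background in either group. Gzma lost its call without any subcutaneous array, lung replicate 1 or lung replicate 2 (adjusted p = 0.0602 to 0.103). The mesothelium gene Bnc1 lost it without any array but subcutaneous replicate 3 (0.053 to 0.156). The muscle gene Mylpf lost it without dish replicate 2, any subcutaneous array, or lung replicate 2 or 3 (0.0629 to 0.144). By limma, 0 members were called in the lists of ciliated cells (1 of 9 at an unadjusted p under 0.05), endothelium (0 of 12), neutrophils (1 of 11), B and plasma cells (0 of 9), smooth muscle and pericytes (2 of 11), keratinocytes (1 of 10), adipocytes (3 of 9), and erythroid cells and platelets (1 of 6). In each of these lists the 2 genes with the largest changes were not well above background in either group. The absence of calls there therefore says little about whether such cells were present. With 1 array left out, calls appeared for Cldn5 (0.86, adjusted p = 0.0459 without lung replicate 3), S100a9 (-1.26, 0.0292 without subcutaneous replicate 3), Lipe (-1.69, 0.00737 without lung replicate 2) and Plin1 (-1.21, 0.0424 without subcutaneous replicate 2). With the long-mRNA covariate 1 appeared for Alas2, lung against subcutaneous (1.45, adjusted p = 0.0493). Median, mean and test differed in sign for the alveolar type I (median -0.31, mean 0.23), monocyte and macrophage (0.07, -0.12), keratinocyte (0.19, -0.02) and MHC class II lists (0.18, -0.13). The test ran upward for epithelial identity, against a median of -0.12, and downward for the inflammatory cytokine list, against a median of 0.13.

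The comparison of lung with dish samples showed what differed from culture once the cells had grown in the lung. Sftpc rose by 9.67 (at least 7.71, adjusted p = 1.85e-06) and Sftpa1 by 5.77. The immediate early transcription factor Fosb rose by 6.07, from 5.84 ± 0.52 to 11.92 ± 1.95 (SD, n = 3), Ly6c1 by 6.64, the antiviral deaminase Apobec3 by 5.36, the proteoglycan Dcn by 5.15, Il24 by 4.85, and Crip1 by 4.73 (at least 4.0). In dish samples Sftpa1, Fosb, Ly6c1 and Il24 were not well above background, so the rises are at least 2.57, 4.49, 4.64 and 3.66. Without lung replicate 3 the bound for Sftpa1 is 1.62. The largest falls were those of the glycoprotein Gpnmb, from 12.55 ± 0.47 to 7.08 ± 0.23 (-5.46, adjusted p = 1.09e-06), the matrix metalloprotease Mmp3 (-5.13), the transcriptional inhibitors Id3 (-3.92) and Id2 (-3.73), the alcohol dehydrogenase Adh7 (-2.86, at least 1.40) and the mesenchymal transcription factor Snai2 (-2.53). Of 19505 genes 1322 differed, 938 higher in lung and 384 lower, and 1167 by at least 2-fold. The share that was higher depended on the scaling: it was 71.0% with the deposited values and 54.5% after quantile normalization, with 662 higher and 553 lower. The count was 514 without dish replicate 2, 667 without dish replicate 3, 591 without lung replicate 1 and 765 without lung replicate 2. It was 3039 with array weights, 856 with RIN as a covariate and 228 with the level of very long mRNAs as a covariate. Both covariates differ between lung and dish samples, so these lower counts do not show that the lost calls are technical.

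Early response genes were higher in the lung than in the dish. Of 13 immediate early genes 7 rose and 0 fell, with 9 higher and 1 lower adjusted over the list alone, among them Ier3 (2.71, at least 1.15) and the phosphatase Dusp1 (2.67). The median was 1.75 (camera adjusted p = 2.75e-08, adjusted p = 0.455 with an estimated correlation). The labels name isolation of GFP-positive cells for the transplanted groups and not for the dish cultures. Antigen presentation genes were higher as well: 5 of 11 MHC class I genes rose and 0 fell, with 6 adjusted over the list alone, such as the nonclassical H2-T23 (2.86, at least 0.94), the immunoproteasome subunit Psmb8 (2.15) and B2m (1.51). The median was 0.89 (camera adjusted p = 2.95e-05, adjusted p = 0.448 with an estimated correlation). H2 genes belong to a family of close copies, so their separate values are uncertain. In the alveolar type II list 5 of 11 genes rose and 0 fell, with 7 adjusted over the list alone. Among the 5, Sftpb (2.65) and Cxcl15 (3.06) were above background on lung replicate 3 alone, and Slc34a2 (1.41, adjusted p = 0.0499) on no array. The median was 1.02 (camera adjusted p = 4.34e-07, adjusted p = 0.448 with an estimated correlation). The airway secretory list passed (adjusted p = 0.0342, adjusted p = 0.628 with an estimated correlation) with 1 of 10 genes higher, Scgb1a1 (5.51, at least 2.52), and 2 adjusted over the list alone. It did not pass without dish replicate 1 (adjusted p = 0.0989) or lung replicate 3 (adjusted p = 0.509), nor with the filter on dim genes (0.149), array weights (0.442) or a fit of the 6 arrays alone (0.0636). Scgb1a1 was under background on lung replicate 1, without which it rose by at least 4.33. Without lung replicate 3 it was 3.64, at least 0.65, and its call was lost without dish replicate 1, 2 or 3 or lung replicate 2 (adjusted p = 0.0583, 0.0522, 0.0706 and 0.051). Sterol synthesis genes rose in 4 of 13 cases and fell in 0 (6 adjusted over the list alone), such as Fdft1 (1.18, adjusted p = 0.14 without dish replicate 2, 0.0876 without dish replicate 3, 0.0903 without lung replicate 2 and 0.0905 without lung replicate 3). The median was 0.82 (camera adjusted p = 0.00308, adjusted p = 0.567 with an estimated correlation). That list did not pass without lung replicate 3 (adjusted p = 0.132) or with array weights (0.127).

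Glycolysis genes were lower in the lung than in the dish: 4 of 11 fell and 0 rose, with 7 adjusted over the list alone, among them lactate dehydrogenase, Ldha (-1.57). The median was -0.79 (camera adjusted p = 7.53e-05, adjusted p = 0.455 with an estimated correlation). Amino acid stress genes were lower as well, with 6 of 13 falling and 0 rising (8 and 1 adjusted over the list alone), such as the serine synthesis enzymes Phgdh (-1.73) and Psat1 (-1.59). The median was -0.90 (camera adjusted p = 7.07e-05, adjusted p = 0.455 with an estimated correlation). The DNA replication list shifted downward, with 1 of 14 genes lower, Mcm5 (-0.91), and 3 adjusted over the list alone. The median was -0.46 (camera adjusted p = 0.00262, adjusted p = 0.511 with an estimated correlation). Without dish replicate 1 the list did not pass (adjusted p = 0.0551), and Mcm5 lost its call without any 1 of the 6 lung and dish arrays (adjusted p = 0.0589 to 0.107). The mitosis list did not pass and had a median of -0.11 and a mean of 0.36, with an upward test (adjusted p = 0.876). The kinase Aurka fell (-1.48), while Cenpe, with its very long mRNA, was 2.97 higher, a call lost without any 1 of the dish or subcutaneous arrays, lung replicate 1 or lung replicate 2 (adjusted p = 0.0503 to 0.177). In all 8 of 40 lists passed, 5 upward and 3 downward, 5 of them also among the 6 that fry found to move on balance one way, and 0 passed with an estimated correlation (lowest adjusted p = 0.448 with an estimated correlation), where 3 had an unadjusted p under 0.05.

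Single members rose or fell in further lists that did not pass between lung and dish samples (adjusted p = 0.0810 to 0.965). They include the protease gene Adam8 (3.56, above background on lung replicate 3 alone) and the urokinase receptor Plaur (2.14) in the matrix protease list (4 of 12 rose, 2 fell), Bst2 (3.64) in the type I interferon response list (1 of 13), and the NF-kB inhibitor Nfkbia (3.30) and the chemokine Cxcl2 (3.82, at least 2.15) in the inflammatory cytokine list (2 of 16). The cell cycle inhibitor Cdkn1a (2.18) rose in the p53 target list, Krt18 (2.33, at least 0.62, or 1.03 and 0.31 without lung replicate 2 and 3) in the epithelial identity list, Cldn18 (3.03, at least 1.39) in the alveolar type I list, and the muscle light chain Mylpf (2.09, at least 0.83) in the skeletal muscle list. Id1 fell (-1.66) and Bhlhe40 rose (1.46, at least 0.82) among the TGF-beta targets. In the hypoxia list 2 of 13 fell, such as Kdm3a (-1.43), and the list passed without subcutaneous replicate 2 (adjusted p = 0.0487). Other settings under which it passed were quantile normalization (0.0175), RIN as a covariate (0.00171) and the long-mRNA covariate (0.00655). Leaving out 1 array also let pass the unfolded protein response list (without dish replicate 1 or 2, adjusted p = 0.00431 and 0.033), the type I interferon response list (dish replicate 2 or lung replicate 2, 0.0281 and 0.0301), the monocyte and macrophage list (dish replicate 3 or lung replicate 2, 0.0496 and 0.00707), the interferon-gamma response list (dish replicate 3, 0.0383) and the collagen list (lung replicate 3, 0.0368). After quantile normalization more lists passed, among them endothelium (0.0446), monocyte and macrophage (0.012) and epithelial identity (0.0268). So did MHC class II with the long-mRNA covariate (0.00422). Median, mean and test differed in sign for the ciliated (0.08 and -0.09), fibroblast (-0.07 and 0.47), complement (-0.04 and 0.10), p53 target (-0.06 and 0.04) and MHC class II lists (-0.16 and -0.07, with an upward test).

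**Figure D2:**
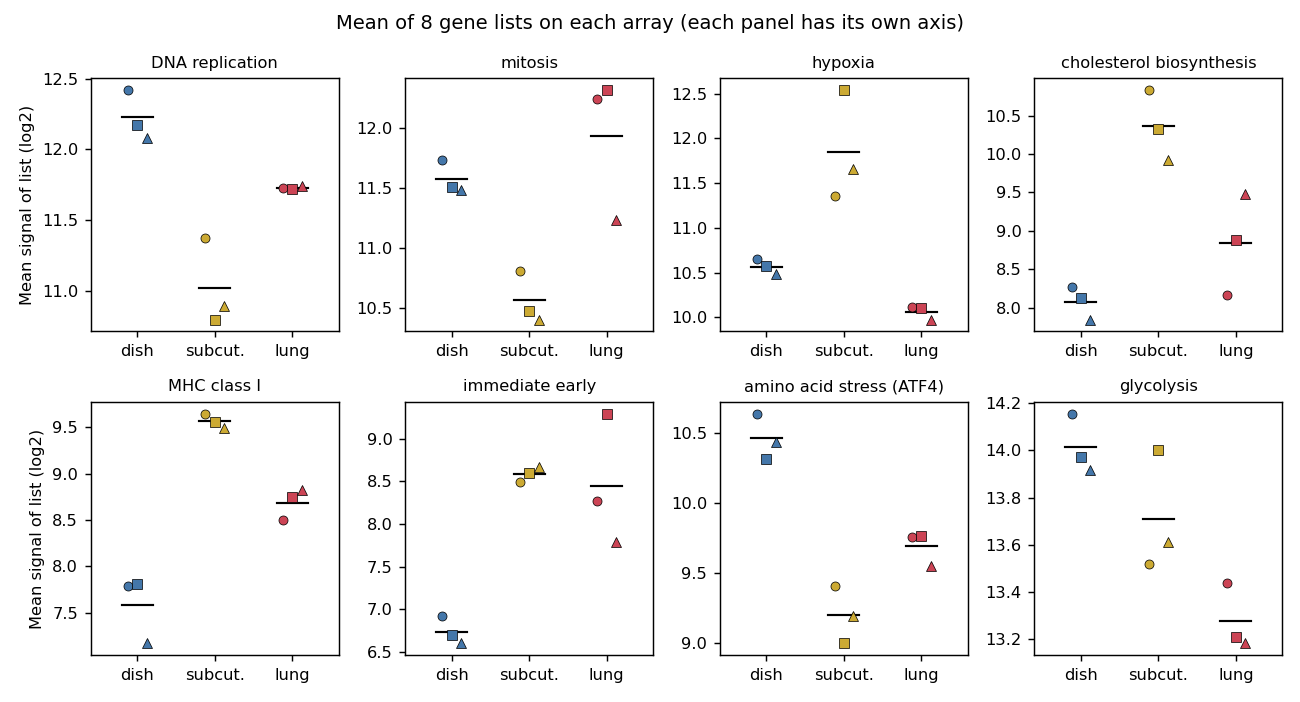
Mean log2 signal of 8 gene lists on each of the 9 arrays (points, 1 per array; circles, squares and triangles are replicates 1, 2 and 3; black lines, group means; each panel has its own axis, none starting at 0). The mitosis list is lower on lung replicate 3 than on lung replicates 1 and 2, and the hypoxia list is highest on subcutaneous replicate 2.

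The comparison of subcutaneous with dish samples showed what differed from culture in the other site. Ly6c1, a surface antigen gene, had the largest rise, from 5.42 ± 0.81 to 17.58 ± 0.11 (SD, n = 3; at least 10.16, adjusted p = 3.09e-09). Ly6c2 rose by 8.07, the proteoglycans Dcn by 9.59 and Lum by 7.40, Dkk2 by 6.71, the urea transporter Slc14a1 by 5.93, Apobec3 by 5.46 and the keratin Krt18 by 5.31. In dish samples Ly6c2, Lum, Dkk2 and Krt18 were not well above background, so these rises are at least 6.58, 5.77, 4.23 and 3.60. Id3 fell from 13.03 ± 0.06 to 6.21 ± 0.30 (-6.82, at least 5.53, adjusted p = 2.61e-06), Gpnmb by 5.24, the arginine methyltransferase Prmt7 by 4.14, the HSP90 co-chaperone Ahsa1 by 3.78, the mitochondrial protease Lonp1 by 3.58, Mmp3 by 3.54 and the Hippo kinase Lats2 by 3.35 (at least 0.73). In all 2513 of 19505 genes differed, 1251 higher and 1262 lower in subcutaneous samples, 2034 of them by at least 2-fold. The count was 1639 without dish replicate 2 and 1280 with RIN as a covariate.

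Sterol synthesis and antigen presentation were the lists with the largest upward shifts under the skin. In the cholesterol biosynthesis list 11 of 13 genes rose and 0 fell, with 12 adjusted over the list alone, such as Fdft1 (3.73), Msmo1 (3.52), Dhcr7 (3.24, at least 2.04) and Fdps (3.07). The median was 2.24 (camera adjusted p = 3.40e-12, adjusted p = 0.237 with an estimated correlation). Of 11 MHC class I genes 9 rose and 1 fell, with 10 and 1 adjusted over the list alone, such as B2m (3.04), Psmb8 (2.94), Psmb9 (2.85, at least 0.89, or 0.58 without subcutaneous replicate 1) and H2-K1 (2.85). The median was 2.52 (camera adjusted p = 3.31e-09, adjusted p = 0.225 with an estimated correlation). The interferon-gamma response list rose with it, 2 of 12 genes higher and 0 lower (4 adjusted over the list alone), the GTPase Igtp among them (1.52, not well above background in either group), but not without dish replicate 1 (adjusted p = 0.0549). The median was 0.61 (camera adjusted p = 0.0132, adjusted p = 0.237 with an estimated correlation). Of 13 immediate early genes 7 rose and 0 fell, with 11 adjusted over the list alone, such as Fosb (5.08, at least 3.49), Jun (2.67) and Atf3 (2.51). The median was 1.74 (camera adjusted p = 5.40e-09, adjusted p = 0.243 with an estimated correlation). Here too the labels name isolation of GFP-positive cells for the transplanted group and not for the dish cultures. In the hypoxia list 6 of 13 rose and 0 fell, with 9 adjusted over the list alone, such as Ndrg1 (4.37), Ankrd37 (2.42) and Egln3 (2.32). The median was 1.10 (camera adjusted p = 6.14e-06, adjusted p = 0.283 with an estimated correlation). Hypoxia genes were highest on subcutaneous replicate 2, the sample with the lowest RIN, 7.5. Among 13 fibroblast markers 3 rose, Dcn, Lum and Dpt (2.35, at least 0.66, or 0.43 without subcutaneous replicate 1), and 0 fell, with 3 adjusted over the list alone. The median was 0.43 (camera adjusted p = 0.00162, adjusted p = 0.237 with an estimated correlation). The collagen and extracellular matrix list had 4 of 15 genes higher and 0 lower, with 7 adjusted over the list alone, among them Postn (3.47, at least 0.60, or 0.19 without subcutaneous replicate 3) and Thbs2 (2.24). The median was 0.79 (camera adjusted p = 0.00104, adjusted p = 0.243 with an estimated correlation). The complement list rose too, with 2 of 7 genes higher, C2 (1.49) and C1s1 (1.36), both not well above background in either group, and 4 adjusted over the list alone. The median was 0.92 (camera adjusted p = 0.00741, adjusted p = 0.237 with an estimated correlation).

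**Figure D3:**
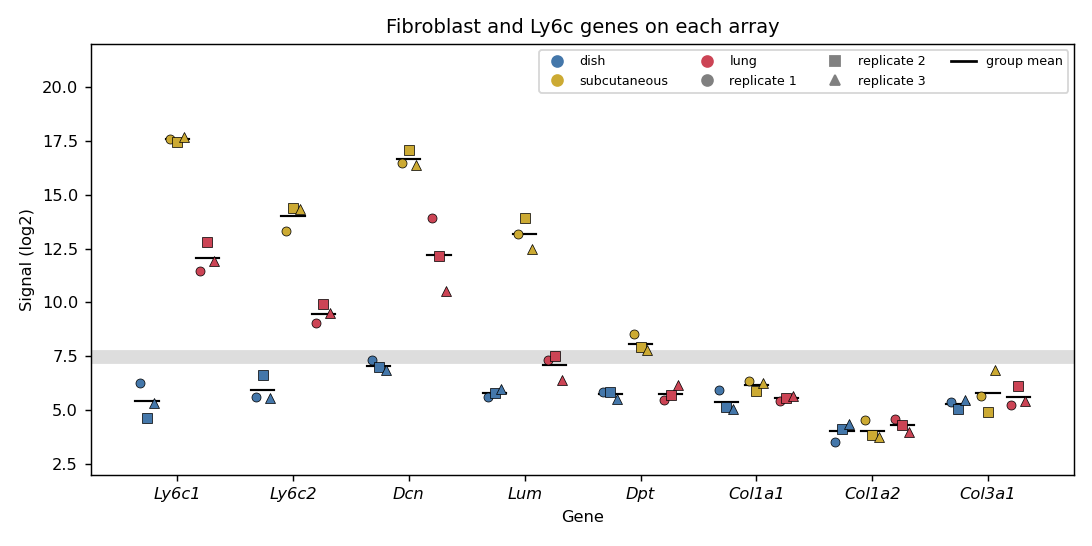
Log2 signal on each of the 9 arrays for Ly6c1, Ly6c2, the fibroblast markers Dcn, Lum and Dpt, and the collagen genes Col1a1, Col1a2 and Col3a1, which were added after their values were seen (points, 1 per array with a symbol per replicate; black lines, group means). Ly6c1 and Dcn reach 17.58 ± 0.11 and 16.64 ± 0.39 (mean ± SD, n = 3) in subcutaneous samples, while the 3 collagen genes lie under the grey band of negative control 90th percentiles (7.20 to 7.73) on all arrays.

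Genes of cell division, respiration and amino acid supply were lower under the skin than in the dish. The DNA replication list had 9 of 14 genes lower and 0 higher, with 12 adjusted over the list alone, such as Mcm5 (-2.36), Cdc6 (-2.13) and Rrm1 (-1.64). The median was -1.27 (camera adjusted p = 3.67e-09, adjusted p = 0.242 with an estimated correlation). The mitosis list had 8 of 14 lower and 0 higher, with 8 adjusted over the list alone, such as Aurka (-2.34), Cdc20 (-2.00) and Cdk1 (-1.40). The median was -1.17 (camera adjusted p = 3.37e-05, adjusted p = 0.283 with an estimated correlation). Amino acid stress genes fell in 10 of 13 cases and rose in 0, with 13 lower adjusted over the list alone, such as the transporter subunit Slc3a2 (-2.12), Psat1 (-1.92) and Phgdh (-1.67). The median was -1.14 (camera adjusted p = 3.31e-09, adjusted p = 0.225 with an estimated correlation). Respiratory chain genes fell in 5 of 13 cases and rose in 0, with 6 lower adjusted over the list alone, such as Sdha (-1.94, at least 0.83) and Uqcrc1 (-1.48). The median was -0.51 (camera adjusted p = 0.00132, adjusted p = 0.242 with an estimated correlation). In all 12 of 40 lists passed, 8 upward and 4 downward, all 12 among the 17 that fry found to move on balance one way, and 0 passed with an estimated correlation (lowest adjusted p = 0.225 with an estimated correlation), where 8 had an unadjusted p under 0.05.

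Other lists did not pass between subcutaneous and dish samples (adjusted p = 0.143 to 0.998). Mesenchymal identity genes went both ways, with 3 of 9 higher, such as Prrx1 (1.85) and Vim (1.61), and 2 lower, Snai2 (-2.73) and Twist2 (-1.84, at least 1.24). The keratins Krt18 and Krt8 (1.63) were the 2 of 15 epithelial identity genes that rose, and Cdh1 fell (-0.90, not well above background in either group), a call lost when any of the 9 arrays but subcutaneous replicate 2 was left out (adjusted p = 0.0515 to 0.161). In the matrix protease list Plau rose (2.03) and 3 of 12 fell, such as Mmp10 (-2.59), with Plau and Mmp10 not well above background in either group. Among glycolysis genes 3 of 11 fell, such as Tpi1 (-1.33) and Pfkl (-1.23), and 1 rose, and the list passed without subcutaneous replicate 2 (adjusted p = 0.0451). With the long-mRNA covariate the airway secretory (0.0236) and alveolar macrophage lists (0.0237) passed. The p53 target Phlda3 fell (-2.91, at least 1.05), as did the TGF-beta target Id1 (-2.28), while Bhlhe40 (2.11, at least 1.46), Bst2 (3.54), Nfkbia (3.09), the alveolar type I list's Emp2 (2.02), the mesothelium list's Bnc1 (1.88, at least 1.02, or 0.61 without subcutaneous replicate 2) and the alveolar macrophage list's Plet1 (3.74, at least 2.83) rose. Of the alveolar type II list 1 of 11 genes rose, and Sftpc (-0.08, adjusted p = 0.954) was not well above background in either group. Median, mean and test differed in sign for the alveolar type II (-0.08 and 0.06), alveolar type I (-0.06 and 0.32), dendritic cell (0.06 and -0.12), lung lineage transcription factor (-0.09 and 0.03), epithelial identity (-0.15 and 0.34), matrix protease (0.40 and -0.08), p53 target (0.03 and -0.23) and unfolded protein response lists (-0.02 and -0.06, with an upward test).

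**Figure D4:**
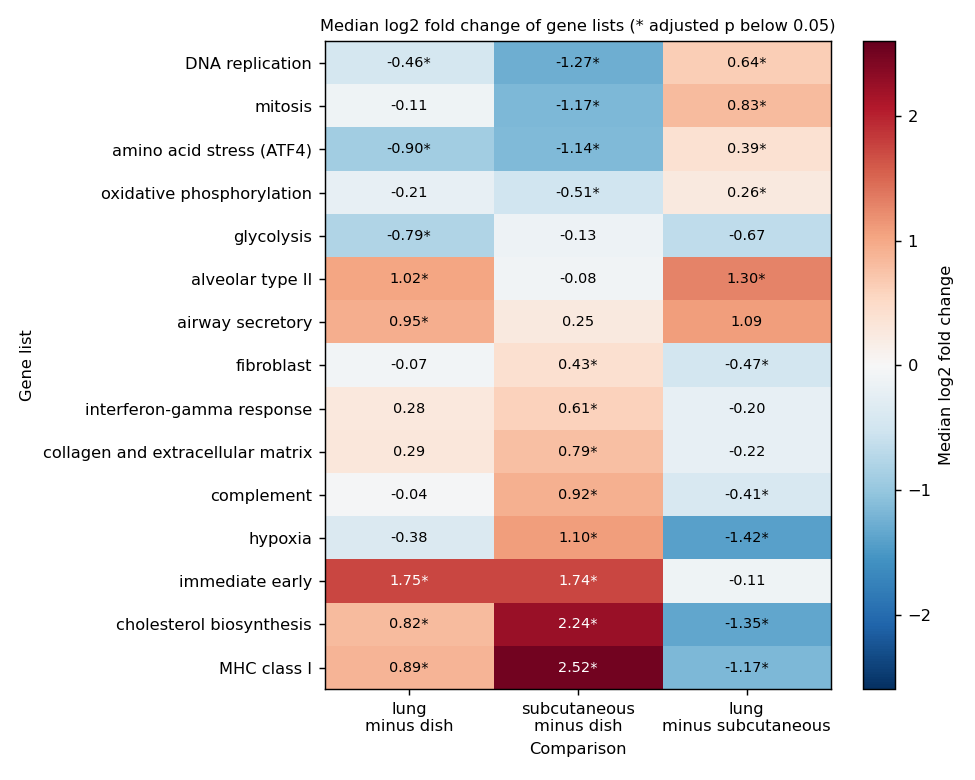
Median log2 fold change of the 15 gene lists that passed in at least 1 of the 3 comparisons (rows), for lung minus dish, subcutaneous minus dish and lung minus subcutaneous (columns; red, higher in the group named first; blue, lower; asterisks, camera adjusted p under 0.05 with the preset correlation). The cholesterol biosynthesis list has medians of 0.82, 2.24 and -1.35, and the hypoxia list -0.38, 1.10 and -1.42.

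Both transplanted groups were then set against the same dish cultures, to see which genes changed in both. By the labels, GFP-positive cells were isolated for both groups, and no such step is named for the dish cultures. A shared change may therefore come from isolation as well as from growth in the animal, and these cannot be told apart here. Ly6c1, Dcn, Ly6c2, Fosb and Apobec3 had the largest mean fitted rises among genes higher in both, and Gpnmb, Id3, Mmp3, Id2 and Adh7 the largest mean falls among genes lower in both. Apobec3 was 5.46 higher in subcutaneous and 5.36 higher in lung samples, and Dcn 9.59 and 5.15. Ly6c1, Ly6c2 and Fosb were not well above background in dish samples, so the order among these genes rests partly on background, and the same holds for Adh7 in both transplanted groups and Id3 in subcutaneous samples. The 3 rises are at least 10.16, 6.58 and 3.49 in subcutaneous and 4.64, 2.06 and 4.49 in lung samples. In all 517 genes changed in the same direction, 369 upward and 148 downward, and 22 in opposite directions. Independent lists of the same lengths would share 60.2, 24.8 and 85.3. Unchanged groups simulated against the same controls shared 0.0200 genes in the same direction on average (at most 1) and 0 in opposite directions. No gene was changed in these simulations, so few calls and an overlap near 0 were set in advance. They do not show what shared controls add where both groups change. The correlation of the log2 fold changes over genes was 0.437, under the 0.50 that shared controls alone gave in the simulations, and their covariance was 0.198 against a simulated 0.0466, a difference of 0.151. A correlation near 0.50 follows from shared controls where no gene changes, and changes in 1 group alone lower it, so 0.437 decides nothing. With 3 dish arrays the controls could not be split, so part of the excess over independent lists may come from the shared controls. Of the 22 genes, 15 were higher in lung and lower in subcutaneous samples, such as the importin Ipo13 (1.17 and -2.43, the latter at least 0.79) and the retinoic acid binding protein Crabp2 (1.31 and -1.62). The other 7 ran the reverse way, such as Thbs2 (-1.89, at least 0.15, and 2.24), the ribosomal protein Rpl39, a gene with many processed copies (-0.98 and 2.80) and xanthine dehydrogenase, Xdh (-1.55 and 1.39). The count in the same direction was 228 without dish replicate 2, 289 without dish replicate 3, 285 without lung replicate 1 and 325 without lung replicate 2, and 776 with array weights, 281 with RIN and 134 with the long-mRNA covariate. The count in opposite directions was 8, 4 and 3 without dish replicate 1, 2 and 3, and 4, 9 and 55 without lung replicate 1, 2 and 3. It was 37 with an intensity trend, 67 with array weights, 7 with RIN, 4 with the long-mRNA covariate and 12 at 2-fold.

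**Figure D5:**
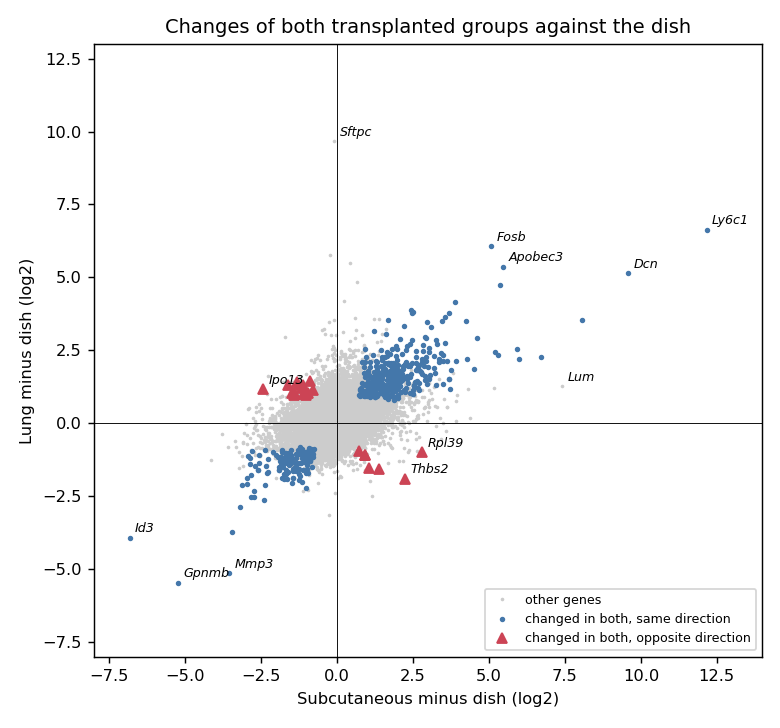
Log2 fold change of lung against dish samples (vertical axis) against that of subcutaneous against dish samples (horizontal axis) for all 19505 genes (points). Blue points are the 517 genes changed in both in the same direction, red triangles the 22 changed in opposite directions, and grey points all others; Sftpc lies high on the vertical axis at 9.67 and near 0 on the horizontal one.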

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

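Of the tests in this part, that of mRNA length had its prediction written before its result was seen, and that of dividing cells was chosen after. Thbs2, Ipo13, Rpl39, Xdh and Crabp2 stood out because they changed against dish in opposite directions in the 2 transplanted groups. Choosing genes called in opposite directions against the same dish arrays fixes a difference between these groups, so the adjusted p values below restate that choice and are no separate test. Lung minus subcutaneous, the matrix protein Thbs2 differed by -4.14 (at least 2.40, adjusted p = 2.57e-05) and the importin Ipo13 by 3.60 (at least 1.95, adjusted p = 2.87e-05). Rpl39 differed by -3.78 (adjusted p = 1.38e-05), Xdh by -2.95 (adjusted p = 0.000615) and Crabp2 by 2.93 (adjusted p = 0.000113). For each gene all 3 arrays of 1 group lay above all 3 of the other. The same held for 2858 of the 2927 genes called and for 32.5% of all genes, so it adds nothing to the choice.

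The hypoxia list ran upward in subcutaneous samples (median 1.10 against dish, adjusted p = 0.283 with an estimated correlation) and had a median of -0.38 in lung samples. The list's difference between lung and subcutaneous samples had a camera adjusted p = 3.40e-08 (adjusted p = 0.471 with an estimated correlation). The mean of the hybridization controls, which the comparisons do not use, was 0.824 higher on the subcutaneous than on the dish arrays. Among the 2634 gene features without a gene name here, 288 were called between lung and subcutaneous samples, 138 of them higher in lung.

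The mitosis list fell in subcutaneous samples against dish (median -1.17, adjusted p = 0.283 with an estimated correlation), had a median of -0.11 and an upward test in lung samples, and differed between lung and subcutaneous samples with a camera adjusted p = 1.87e-05 (adjusted p = 0.471 with an estimated correlation). Mki67 and Cenpe, 2 of its members with very long mRNAs, were 5.10 and 4.09 higher on lung replicates 1 and 2 than on lung replicate 3. Against more dividing cells on replicates 1 and 2 as the cause stands the median of 25 other division genes, 0.0198 (quartiles -0.06 and 0.39). A candidate explanation that remains is the length of the mRNA, through labelling or amplification that differed between arrays: 75 genes with very long coding sequences had a median of 0.971, 66 of them higher on replicates 1 and 2, and the highest of 10000 random lists matched on level had 0.363. A true difference in these transcripts between the lung samples stays open and untested, and so does a lower rate of division under the skin than in the lung, which would also raise shorter genes such as Cdc20 (2.83) and Plk1 (1.53) in lung samples.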

How the results depend on the processing

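No alternative moved the median of all genes by over 0.1, and every alternative other than the covariate for very long mRNAs was set before the data were examined. Only 28.0% to 34.4% of genes lay above the background guide on each array, so that median rests mostly on dim genes. It says little about expressed genes: quantile normalization took the share of lung against dish calls that was higher from 71.0% to 54.5%. Of 249 calls of named genes, quantile normalization ended 12, array weights 6, an intensity trend 5, RIN as a covariate 36, the replicate block 11, a fit of the 6 arrays alone 23, the mean of features 0, leaving out 1 array 19 to 40, and the covariate for very long mRNAs 78; the filter on dim genes ended 0 of 242. The 1 reversal was that of Cenpe, lung against dish, at -0.15 with that covariate (adjusted p = 0.979, against 3.83e-05 to 0.177 over its other alternatives), whose mRNA is itself very long. Of the 30 list calls, 0 held with the estimated correlation, in each comparison, and 0 to 4 were lost under each other setting.

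Genes called in lung against subcutaneous samples numbered 1110 with the long-mRNA covariate, and 1476 to 2928 with 1 array left out. In lung against dish they numbered 3039 with array weights, 856 with RIN and 228 with the long-mRNA covariate, and 514 to 1442 with 1 array left out. In subcutaneous against dish they numbered 1280 with RIN, and 1639 to 2738 with 1 array left out. With the replicate number as a block, which does not pair the samples (r of residuals -0.0567 to 0.0854 for the same number, -0.138 to 0.0977 for others), they numbered 2852, 1313 and 2475. Lists called in lung against dish numbered 15 after quantile normalization and 14 with the long-mRNA covariate. With 1 array left out, 6 to 12 lists were called in lung against subcutaneous, 7 to 10 in lung against dish and 11 to 13 in subcutaneous against dish. Genes changed in both transplanted groups in the same direction numbered 776 with array weights, 281 with RIN and 134 with the long-mRNA covariate, and 228 to 502 with 1 array left out. In opposite directions they numbered 37 with a trend, 67 with weights, 7 with RIN, 4 with the long-mRNA covariate and 12 at 2-fold, and 3 to 55 with 1 array left out. The cause of these shifts was not tested, and as RIN and the long-mRNA level differ between the groups, these covariates also take away part of the group differences. On each array 28.0% to 34.4% of genes were above the background guide, which limits what could be seen for the rest.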

Other observations

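A further set of genes differed between some or all of the 3 groups. Il24, a cytokine of the interleukin-10 family, was higher in lung than in subcutaneous (4.18, at least 3.57) and dish samples (4.85, at least 3.66), with 0.67 between subcutaneous and dish samples (adjusted p = 0.43). The keratin Krt18 was at 5.72 ± 0.39 (SD, n = 3) in dish, 8.04 ± 0.74 in lung and 11.03 ± 0.03 in subcutaneous samples, and the surface protein gene Plet1 at 6.51 ± 0.36, 8.34 ± 0.81 and 10.26 ± 0.39. Both were called in all 3 comparisons. Phlda3, a p53 target, was at 8.56 ± 0.40 in dish, 9.08 ± 0.27 in lung and 5.65 ± 0.36 in subcutaneous samples, and was not called between lung and dish (adjusted p = 0.304). The helix-loop-helix inhibitors Id1, Id2 and Id3 fell in both transplanted groups, by 1.66, 3.73 and 3.92 in lung and by 2.28, 3.45 and 6.82 (at least 5.53) in subcutaneous samples. In lung samples against dish, the cell cycle gene Cdk2ap2 rose by 4.16, the endoplasmic reticulum gene Creld2 by 2.25, and the methyltransferase Nnmt fell by 2.37. In subcutaneous samples against dish, the LIM domain gene Crip1 rose by 5.36 (at least 4.62) and Wdr18 fell by 3.31.

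The tests of host lung epithelium, lung lineage factors, fibroblasts, and monocytes or endothelium were chosen after the results were seen, and the splits of the samples were set before.

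Surfactant and airway secretory transcripts were high on the lung arrays, Sftpc at 15.14 ± 1.51 (SD, n = 3). A candidate source is RNA or cells of host lung epithelium carried into the sample, although isolation of GFP-positive cells is meant to remove such cells. How far the isolation removed host cells or their RNA was not tested. The 9 genes had a median SD of 1.05 between the lung arrays. For random lists of other genes called higher, drawn from the 20 matched to each on fold change, it was 0.530 (percentile 93.95). Sftpc (9.76), Sftpa1 (6.01) and Scgb1a1 (5.08) had few genes near them, since only 20 reached a log2 fold change of 3. Their matches therefore rose mostly by less, and this comparison does not decide the source. The answer also depends on the genes drawn from: several sets were tried, with percentiles of 99.95 (948 genes), 98.6 (222), 92.6 (73) and 33.4 (20). Of other type II cell genes, named after their values were seen, Lamp3 and Napsa were not well above background on any array and so decide nothing, and the lipid transporter Abca3 differed by -0.53 between lung and subcutaneous samples (adjusted p = 0.289). For a lung lineage programme in the tumour cells, 0 of 10 factors rose in either comparison with lung, but 1 of the 10 was above background on the dish arrays, so host carry-over and such a programme cannot be told apart.

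Dcn, Lum, Ly6c1 and Ly6c2 were high in subcutaneous samples, Dcn at 16.64 ± 0.39 (SD, n = 3) and Ly6c1 at 17.58 ± 0.11. Host fibroblasts may bring Dcn and Lum, although isolation of GFP-positive cells is meant to remove them, which was not tested. The abundant fibroblast genes Col1a1, Col1a2 and Col3a1 had a highest upper 95% bound of 1.41 against dish, but 0 of the 3 read above background in any group, so the features decide nothing, and Dpt (2.35, at least 0.66) and Postn (3.47, at least 0.60) rose with Dcn. Host monocytes or endothelial cells may bring Ly6c1 and Ly6c2: of 25 other markers the largest difference was 1.43, for Cdh5 (adjusted p = 0.0837), and 1 was called, Ramp2 (1.25, adjusted p = 0.0193, but 0.078 without dish replicate 2 and 0.0729 without subcutaneous replicate 3), but only 1 of the 25, Lyz2, read above background in any group. Host cells and expression in the tumour cells therefore cannot be told apart for these genes, and the latter was not tested.

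Other splits of the samples were counted, with fits of the 6 arrays compared. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For lung against subcutaneous samples 2301 genes and 10 lists were called, and at most 0 genes and 9 lists in another split, so 1 of 10 splits gave as many genes and 1 as many lists. For lung against dish the values were 1294 genes and 7 lists, with at most 0 and 10 in another split, and 1 and 4 splits gave as many. For subcutaneous against dish they were 2312 genes and 12 lists, with at most 0 and 9, and 1 split gave as many of each. For the genes changed in both transplanted groups, 100 of the 840 splits of the 9 arrays were drawn. As many genes in the same direction as the real 517 came from 2 of the 100, the real one included, and as many in opposite directions as the real 22 also from 2. Of the 100, 93 gave 0 genes in the same direction and 98 gave 0 in opposite directions, so the real counts were set mostly against 0, and whether chance can be excluded is left open. The 22 lie below the 85.3 of independent lists. The other split with 754 in the same direction kept the 3 subcutaneous arrays as the shared reference and mixed dish with lung arrays, which follows the distance of the subcutaneous arrays from all others. The one with 83 in opposite directions holds the 3 true groups with lung as the reference, and so the structure of the study itself.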
